A study of Sinorhizobium meliloti with 12 samples.

How the data were processed

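The series holds 12 libraries of total RNA from Sinorhizobium meliloti 1021, 3 for each of WT and the cspA2 cspA4 double deletion in exponential free-living culture and in symbiotic nodule tissue at 28 dpi, prepared with a stranded total RNA kit per the labels' protocols. Reads were aligned with TopHat and compared with Cuffdiff per the submitters' processing notes, with versions and genome build not given in the sources used here. The labels do not say whether replicates came from separate cultures or plants, so p-values measure the spread between samples. The authors deposited 1 table per growth condition, each with both genotypes. Each table holds expected counts and FPKM per library as deposited by the authors, the FPKM of each group, which equals the mean of its 3 libraries within 0.1% for 100% of the features, and the p-value and q-value that the authors obtained with Cuffdiff. The authors' columns of log2 fold change and test statistic hold spreadsheet errors and were not used, and log2 ratios for the authors' deposited table were computed from its group FPKM. The fragments with no feature name (0.003% to 0.012% per library) were left out of library sizes and tests.

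Expected counts as deposited by the authors were fractional for 80 to 128 features per library and were rounded. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling, the filterByExpr filter, genotype as the only factor and a separate fit for each growth condition. Benjamini-Hochberg adjusted p of at most 0.05 called a change, over 6482 features in culture and 6361 in nodules. Log2 fold changes are those of this fit, and their SE was taken as the absolute log2 change divided by the square root of the F statistic. The plan written before the data were examined named the authors' Cuffdiff calls as the main test, with limma on log2(FPKM + 1) in case the files held values per library. edgeR took their place because the files hold expected counts per library, after first fits had been seen, and results of the authors' deposited table are given beside it. Alternatives planned for the authors' p-values were applied to those of edgeR.

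The 28 gene lists were drawn up before the data were examined, from gene symbols. They were compared with Fisher's exact test, two-sided, of called members against all other tested features except non-coding RNAs, with Benjamini-Hochberg adjustment over the lists. This test treats genes as independent, which they are not. A list's median log2 change was placed among 10000 random lists of the same size drawn from 20 bins of mean FPKM. The random lists were not matched on replicon. Camera with the preset correlation of 0.01 and with an estimated correlation, and fry, all from limma 3.58.1, were run as additional set tests. The replicons were told apart by the letters of the locus tags, and Fisher's exact test was adjusted over 3 replicons and 2 conditions. Overlap between the conditions was tested with Fisher's exact test over features tested in both. Expression in nodules and in culture was compared by the group FPKM of the authors' deposited table as a description, and by limma voom with a spread for each group, chosen after the data were seen.

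The genes named in the text follow a rule fixed before the data were examined, with exceptions stated where they occur. The rule takes all csp genes, the 10 largest rises and 10 largest falls among calls with FPKM of at least 10 in the higher group, and up to 4 called members of each list or else its 2 most abundant members. It also takes up to 5 genes in each direction of the overlap. rRNA and tRNA were not ranked.

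Depth ranged from 4337002 to 16111931 assigned fragments in culture and from 5432469 to 11052783 in nodules. In a simulation with the counts' own spread, 96% of 2-fold and 100% of 4-fold changes were found in culture with 6.22% false calls. In nodules 0% and 58% were found with 7.94% false calls. The interaction test found 50% of 4-fold changes with 1.96% false calls. All features were simulated independently, so these rates do not cover shifts shared by many genes of a library. Random lists of 25 genes gave a Fisher p under 0.05 in 1.5% of cases. Alternatives left out each library, changed the threshold, fold, filter, scaling and pseudocount, added the replicate number as a block, thinned libraries to the same depth, and used DESeq2 1.42.0, limma on log2(FPKM + 1) or the authors' calls. List and overlap statistics were computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. GC content could not be checked, since no genome sequence was used here.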

Results

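Total RNA of Sinorhizobium meliloti 1021, a soil bacterium that fixes nitrogen inside legume root nodules, was sequenced in 12 libraries that form 4 groups of 3. The wild type (WT) and a mutant lacking cspA2 and cspA4, which encode small RNA-binding cold shock proteins, were each sampled as free-living cells in exponential growth and in nodule tissue 28 days after inoculation. The free-living WT libraries held 13912363, 16111931 and 11233759 assigned fragments, and the free-living mutant libraries 5182681, 7350005 and 4337002, so depth differed with genotype. The nodule libraries held 8752578, 7317754 and 6997047 fragments in the WT and 11052783, 8069581 and 5432469 in the mutant. The RNA of ribonuclease P (rnpB) took 12.6% to 28.8% of the nodule fragments and 1.33% to 2.55% of the free-living ones. The non-coding RNA SMc07091 took 10.2% of the fragments in WT nodule replicate 1 and between 0.809% and 1.74% in the other nodule libraries. The 95% Wilson intervals of these shares were at most 0.076 percentage points wide, which covers counting error only. Correlations of log counts across features were 0.97 to 0.991 between free-living libraries of the same genotype and 0.759 to 0.824 between nodule libraries of the same genotype.

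The first question was which genes the loss of cspA2 and cspA4 changed in free-living cells. The deleted genes themselves fell, with log2 changes of -12.31 for cspA2 (SE 0.70) and -11.18 for cspA4 (SE 0.68; n = 3 libraries per genotype, edgeR adjusted p = 1.29e-05 for each). cspA2 had 36509, 46369 and 26649 fragments in the WT libraries and 2, 2 and 7 in the mutant libraries, and cspA4 had 66372, 77074 and 40169 against 11, 25 and 8. Among the 5 other cold shock genes, cspA7 fell by 0.44 (SE 0.11, adjusted p = 0.0488). The log2 changes of cspA1 (-0.67, adjusted p = 0.217), cspA3 (-1.08, 0.0603), cspA5 (-0.37, 0.105) and cspA6 (-0.71, 0.0525) did not pass the threshold of 0.05. Adjusted over the list alone, 6 of the 7 cold shock genes fell, against 3 over all genes tested. The call of cspA7 ended without WT replicate 1 (adjusted p = 0.126), WT replicate 2 (0.18), mutant replicate 1 (0.163) or mutant replicate 2 (0.195), whereas those of cspA2 and cspA4 held in each of these fits. Over all genes tested, 6 of the 7 fell without WT replicate 3, 5 without mutant replicate 3 and 6 with DESeq2. The authors' deposited table called 5, among them cspA3 (-1.05) and cspA6 (-1.12).

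**Figure D1:**
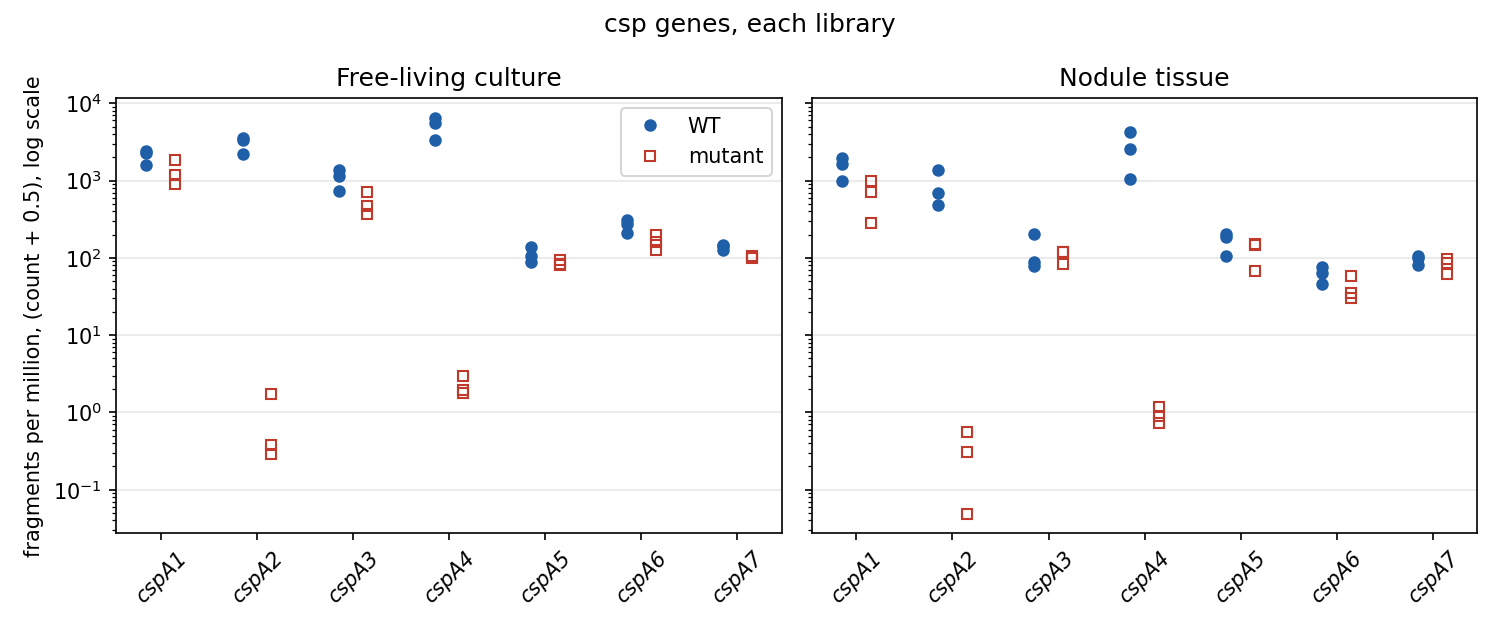
TMM-scaled CPM (with 0.5 added to each count, log axis) of the 7 cold shock genes in each library of free-living culture (left) and nodule tissue (right), with WT as filled circles and the mutant as open squares. In culture cspA2 drops from a mean of 3053 to 0.711 CPM and cspA4 from 5146 to 2.14 CPM, while the points of the 5 other genes lie close together or overlap.

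A sigma factor of the general stress response and its regulators rose in the free-living mutant. rsiA1, annotated as an anti-sigma factor, rose by 1.33 on the log2 scale (SE 0.18, adjusted p = 0.00872), and rsiB1, annotated as an anti-anti-sigma factor, by 1.13 (SE 0.14, 0.00749). The general stress sigma factor rpoE2, whose tag lies beside theirs, rose by 0.72 (SE 0.12, 0.0315) and the heat shock sigma factor rpoH2 by 0.69 (SE 0.11, 0.0315). The glycogen synthase gene glgA2 rose by 0.97 (SE 0.12, 0.00749). The non-coding RNAs SMc06778, with the largest rise (1.68, SE 0.26), SMb23394 (1.08, SE 0.27) and SMa7019 (0.92, SE 0.19) rose, and so did the hypothetical genes SMb20728 (1.29, SE 0.21), SMa1503 (1.05, SE 0.25), SMc00764 (1.01, SE 0.23) and SMc02656 (0.98, SE 0.22). The haem uptake genes hmuV, hmuT and hmuU rose by 0.73, 0.61 and 0.44. Of the general stress and osmoprotection genes 3 of 26 rose and none fell (4 rises adjusted over the list alone), and 9 lay below 0. Of the iron uptake and storage genes 3 of 29 rose (5 rises and 5 falls adjusted over the list alone). The authors' deposited table called none of hmuV, hmuT and hmuU. Of that list it called hmuS higher (0.395) and rirA (-0.888) and fur (-0.496) lower. Neither list was enriched for changed genes (Fisher's exact test, adjusted p = 0.488 and 0.556). The general stress list was enriched at a threshold of 0.01 (2 of 26 called, adjusted p = 0.00829), without WT replicate 1 (2 of 26, 0.0125) and without mutant replicate 1 (3 of 26, 0.000501). The members called there were rsiA1 and rsiB1, joined by rpoE2 in the last of these fits. Their tags adjoin, and the test counts them as independent genes, so these enrichments rest on 1 place in the genome. The general stress list was not enriched with DESeq2 (8 of 26), without mutant replicate 3 (7 of 26, 0.484) or in the authors' deposited table (4 of 26). Without WT replicate 3 its counts were 10 rises and 5 falls (0.254), and those of the iron list 5 rises and 7 falls. Each of the rises named from the main test lost its call without WT replicate 2 (adjusted p of at most 0.189) and without mutant replicate 2 (at most 0.198), and SMb23394 also without mutant replicate 3 (0.0501). Only rsiA1, rsiB1, glgA2, SMb20728 and SMc06778 kept their rise without WT replicate 1. Without mutant replicate 1 only these, rpoE2 and SMc02656 did.

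The largest falls after the deleted genes included those of SMc03100, a hypothetical protein with a signal peptide (-2.03, SE 0.26, adjusted p = 0.00749), the non-coding RNAs SMb23416 (-1.70) and SMb23353 (-1.56), SMc02284 (-1.44) and SMc01427 (-1.42, SE 0.15, 0.00302). mucR, a regulator that shifts cells between motility and exopolysaccharide synthesis, fell by 1.43 (SE 0.31, 0.0475), and visN and visR, the upper regulators of the flagellar genes, fell by 1.27 and 0.64. The glutamine synthetase gene glnA fell by 1.23 (SE 0.28, 0.0475). The tag of SMc01427 directly precedes that of the deleted cspA2, so a local effect of the deletion cannot be told apart for this gene. Without WT replicate 2 or mutant replicate 2 all of these falls except that of SMc01427 lost their call (adjusted p of at most 0.189 and 0.198). Without WT replicate 1 or mutant replicate 1 all except those of SMc03100, SMb23416 and SMc01427 did (at most 0.153 and 0.193).

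In total 379 of 6482 tested features changed in the free-living mutant, 119 up and 260 down (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of at most 0.05), and 2403 had an unadjusted p under 0.05. The calls crowded at the threshold, since 340 of the 379 had an adjusted p over 0.045, and a threshold of 0.01 left 10. The count was 15 without WT replicate 1, 3 without WT replicate 2, 2720 without WT replicate 3, 15 without mutant replicate 1, 3 without mutant replicate 2 and 1206 without mutant replicate 3. Of the 64 called features named here other than cspA2 and cspA4, 9, 1, 64, 10, 1 and 63 kept their call in the same order, and the 1 kept without WT replicate 2 or mutant replicate 2 was SMc01427. The authors' deposited table called 1104 features (229 up, 875 down), 265 of them among the 379, DESeq2 called 1953, and limma on log2(FPKM + 1) called 4. On the first principal component WT replicate 3 (-0.193) and mutant replicate 3 (6.1) lay closest to the other genotype. Leaving out either moved the genotypes further apart, so higher counts without either, also in the lists below, are no independent support. Of chromosomal features 46.2% were called without WT replicate 3, 24.1% without mutant replicate 3 and 37.5% with DESeq2 (38.8%, 12.6% and 22.8% of the others).

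Genes of protein synthesis lay below 0 in the free-living mutant as groups, although few of them passed the test singly. All 54 ribosomal protein genes lay below 0, with a median log2 change of -0.92, and so did all 21 aminoacyl-tRNA synthetase genes (-0.72) and all 19 genes of RNA decay and RNA helicases (-0.75), while 12 of 13 translation factor genes did (-0.91). These medians lay at the percentiles 0.02, 0, 1.68 and 0.13 of random gene lists of the same size and mean FPKM, but camera with an estimated correlation called none of the 4 lists (adjusted p = 0.52 for each). Matched on WT FPKM, in lists that could hold the same genes, the ribosomal protein median lay at percentile 2.27. None of these random lists was matched on replicon. In the highest of 5 bands of mean FPKM the chromosome had a median of -0.62, and pSymA and pSymB 0.12 and 0.05. Percentiles of lists of chromosomal genes may therefore be too extreme. The members that fell were efp, elongation factor P (-1.10, SE 0.24), trpS, tryptophanyl-tRNA synthetase (-0.88, SE 0.23), rbfA, a ribosome maturation factor (-0.94, SE 0.22), and rph, ribonuclease PH (-0.94, SE 0.23). None of the 54 ribosomal protein genes passed over all genes tested or adjusted over the list alone, and the most abundant were rpmH (-0.97, adjusted p = 0.106) and rpmD (-1.13, 0.0551). Adjusted over the list alone, 19 aminoacyl-tRNA synthetase, 13 RNA decay and 10 translation factor genes fell, against 1, 2 and 1 over all genes tested. The authors' deposited table called 39 of the 54 ribosomal protein genes, all of them lower in the mutant. The calls of efp, trpS, rbfA and rph ended without WT replicate 1, WT replicate 2, mutant replicate 1 or mutant replicate 2 (adjusted p of at most 0.153, 0.189, 0.193 and 0.198). Without WT replicate 3, in contrast, 43 of the 54 ribosomal protein genes fell, without mutant replicate 3 32 did (Fisher's exact test, adjusted p = 1.07e-06 and 1.19e-09), and DESeq2 with all libraries called 34. Likewise 20 and 11 aminoacyl-tRNA synthetase, 16 and 11 RNA decay and 11 and 10 translation factor genes fell in these 2 fits. Both fits left out the library of a genotype that lay closest to the other genotype, so their higher counts are no independent support.

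Some genes of aerobic respiration fell in the free-living mutant. The cytochrome oxidases and bc1 complex were the only one of the 28 lists enriched for changed genes in the main test. Other lists passed at a threshold of 0.01 or with a least fold. Of its 29 members 8 fell and none rose (27.6%, against 5.74% of the other features, Fisher's exact test, two-sided, adjusted p = 0.0051), while camera with an estimated correlation did not call the list (adjusted p = 0.52). The 8 included cyoA and cyoC of the cytochrome o ubiquinol oxidase (-1.54, SE 0.28, and -1.23, SE 0.20), ccmD of cytochrome c maturation (-1.54, SE 0.34) and ctaB of haem O synthesis (-1.10, SE 0.28), and 16 members fell adjusted over the list alone. Of the 37 genes of NADH dehydrogenase and ATP synthase 5 fell, among them atpC (-1.29), atpF2 (-1.28), atpE (-1.17) and nuoI (-1.04), with 19 falls and 1 rise adjusted over the list alone. Of the 25 genes of the TCA cycle and dicarboxylate use 3 fell, namely the succinate dehydrogenase genes sdhB (-0.98) and sdhD (-0.90) and lpdA2 (-0.74), with 13 falls adjusted over the list alone. Neither of these 2 lists was enriched in the main test (Fisher's exact test, adjusted p = 0.488 for each), and 12 of the 37 and 4 of the 25 members lay above 0. In the same order both were enriched without WT replicate 3 (0.000504 and 0.000407), without mutant replicate 3 (3.92e-06 and 0.000186) and with DESeq2 (0.00315 and 0.00384), and the first also with a log2 change of at least 1 (0.00683). The authors' deposited table called 17 of the 37 and 15 of the 25, all lower in the mutant (adjusted p = 0.000198 and 1.45e-05). The enrichment of the cytochrome oxidases passed without WT replicate 1 (2 of 29 called, adjusted p = 0.0125), WT replicate 3 (20 of 29, 0.0255) and mutant replicate 3 (15 of 29, 0.000256). It ended without WT replicate 2, mutant replicate 1 or mutant replicate 2, where none of the 29 was called, and at a threshold of 0.01, where again none was. The authors' deposited table called 8 of the 29, against 16.9% of the other features (Fisher's exact test, adjusted p = 0.273). Its largest falls in the list were those of cyoA, ctaD, fbcF and fbcC, so the equal count does not mean the same genes.

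Some genes of the cell envelope, stress response and metabolism changed in the free-living mutant, and none of their lists was enriched with edgeR and all libraries. Of 36 succinoglycan genes 4 fell (10 falls and 1 rise adjusted over the list alone), namely the UDP-glucose pyrophosphorylase gene exoN (-0.99), the glycosyltransferase gene exoA (-0.83) and the regulators exsF (-0.96) and exsI (-0.80). Of 24 genes of galactoglucan and quorum sensing mucR and wgeA (-0.99) fell and wgaJ (0.48) rose, the same number as adjusted over the list alone. Of 17 lipopolysaccharide genes kdsA (-0.74) and kdsB (-0.71), which make and activate the sugar Kdo, fell (12 falls adjusted over the list alone). Of 32 genes of cobalamin and haem synthesis hemE (-0.70), hemF (-0.70), hemH (-0.68) and cobW (-0.73) fell, and 6 fell adjusted over the list alone. Of 36 heat shock and protease genes clpP2 (-0.95), hslV (-0.85) and hslO (-0.84) fell and rpoH2 rose (6 falls and 1 rise adjusted over the list alone), and of 35 oxidative stress genes gst11 (-0.69) and gshB1 (-0.50) fell (9 falls and 2 rises). Of 25 cell cycle genes cpdR2 (-0.98), ftsE (-0.50) and ftsX (-0.45) fell (6 falls and 1 rise adjusted over the list alone). In the polyhydroxybutyrate list phbB, acetoacetyl-CoA reductase (-0.40), fell together with phaF2 (-0.70), which is annotated as a Na+/H+ antiporter subunit, with 6 of 22 falling adjusted over the list alone. Of 25 phosphate starvation genes, with a median of -0.62, only phnW (0.41) changed over all genes tested, while 14 fell and 2 rose adjusted over the list alone. Each of these calls ended without WT replicate 2 (adjusted p of at most 0.189 among the named features lost) and without mutant replicate 2 (at most 0.198), and also without WT replicate 1 or mutant replicate 1. Without WT replicate 3, where 46.2% of chromosomal features and 38.8% of the others were called, the counts rose. They became 17 falls and 1 rise for succinoglycan, 13 falls for lipopolysaccharide and 20 falls and 3 rises for heat shock. Falls and rises were 14 and 4 for oxidative stress, and 15 and 2 for cobalamin and haem. In the same fit they were 10 and 2 for the cell cycle, 7 falls for polyhydroxybutyrate, 3 and 3 for galactoglucan, and 15 and 2 for phosphate starvation. The lipopolysaccharide (adjusted p = 0.0242), heat shock (0.035) and phosphate starvation lists (0.0354) were then enriched. The phosphate starvation and lipopolysaccharide lists were also enriched with DESeq2 (17 of 25, 0.00219, and 12 of 17, 0.00384) and without mutant replicate 3 (15 of 25, 5.37e-05, and 11 of 17, 0.000186). In the authors' deposited table the heat shock (0.00164), oxidative stress (0.00362) and lipopolysaccharide lists (0.0377) were enriched. That table did not call the rises of wgaJ and phnW, since the 3 galactoglucan and 7 phosphate starvation genes it called were all lower.

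Few genes of symbiosis, motility and plasmid transfer passed the test in free-living cells with all libraries. None of 15 nitrogenase, 26 microaerobic respiration, 21 denitrification, 19 chemotaxis, 13 pilus or 17 type IV secretion genes passed over all genes tested with edgeR. Adjusted over the list alone 3 chemotaxis genes (2 rises, 1 fall) and 5 type IV secretion genes (rises) passed, and 0 in the other 4 lists. In the order of the 6 lists DESeq2 called 2, 3, 5, 2, 1 and 5 members, and the authors' deposited table called 2, 2, 4, 2, 1 and 2. These counts of 0 did not hold without WT replicate 3, where 3, 5, 15, 9, 2 and 10 members were called. Among them were 15 of 21 denitrification genes, all higher in the mutant (Fisher's exact test, adjusted p = 0.0354). In that fit 46.2% of chromosomal features and 38.8% of the others were called. The 5 of 26 microaerobic respiration genes were a lower share than elsewhere (Fisher's exact test, adjusted p = 0.038). Without mutant replicate 3 the counts were 2, 3, 2, 2, 0 and 4. All 21 denitrification genes lay above 0 (median 0.33, percentile 99.98), as in napE (0.15, adjusted p = 0.506) and nosL (0.13, 0.522), and 16 of 17 type IV secretion genes did (median 0.33, percentile 99.6), as in traC (0.59, 0.0539) and traD (0.37, 0.236). Of all features of pSymA and pSymB 85.5% and 80.9% lay above 0 too, and the random lists were not matched on replicon. The most abundant members of the other lists were fixX (0.19, 0.319), fdxN (0.05, 0.806), fixQ1 (0.53, 0.188), fixQ2 (0.70, 0.173), cheW3 (-0.75, 0.0536), cheY2 (0.10, 0.635), pilA1 (-0.07, 0.73) and pilA2 (-0.06, 0.867). Of 26 nodulation genes nodN2 (-0.51, SE 0.12) fell, of 37 flagellar and motility genes visN and visR fell, and of 24 nitrogen assimilation genes glnA fell, the same numbers as adjusted over each list alone. These calls ended without WT replicate 1, WT replicate 2, mutant replicate 1 or mutant replicate 2. The authors' deposited table called none of the 26 nodulation genes, and of the 37 flagellar and motility genes only visN. Without WT replicate 3 the counts were 5 rises and 1 fall for nodulation, 11 rises and 3 falls for flagella, and 1 rise and 8 falls for nitrogen assimilation. The camera set test with its preset correlation of 0.01 called 21 of the 28 lists, and 0 with an estimated correlation (adjusted p = 0.435 to 0.733). The directional fry test called only the cold shock genes (adjusted p = 0.04), a list that holds the 2 deleted genes. The mixed fry test, which lets members go either way, called these (adjusted p = 0.00275) and the general stress and osmoprotection genes (0.0054).

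**Figure D2:**
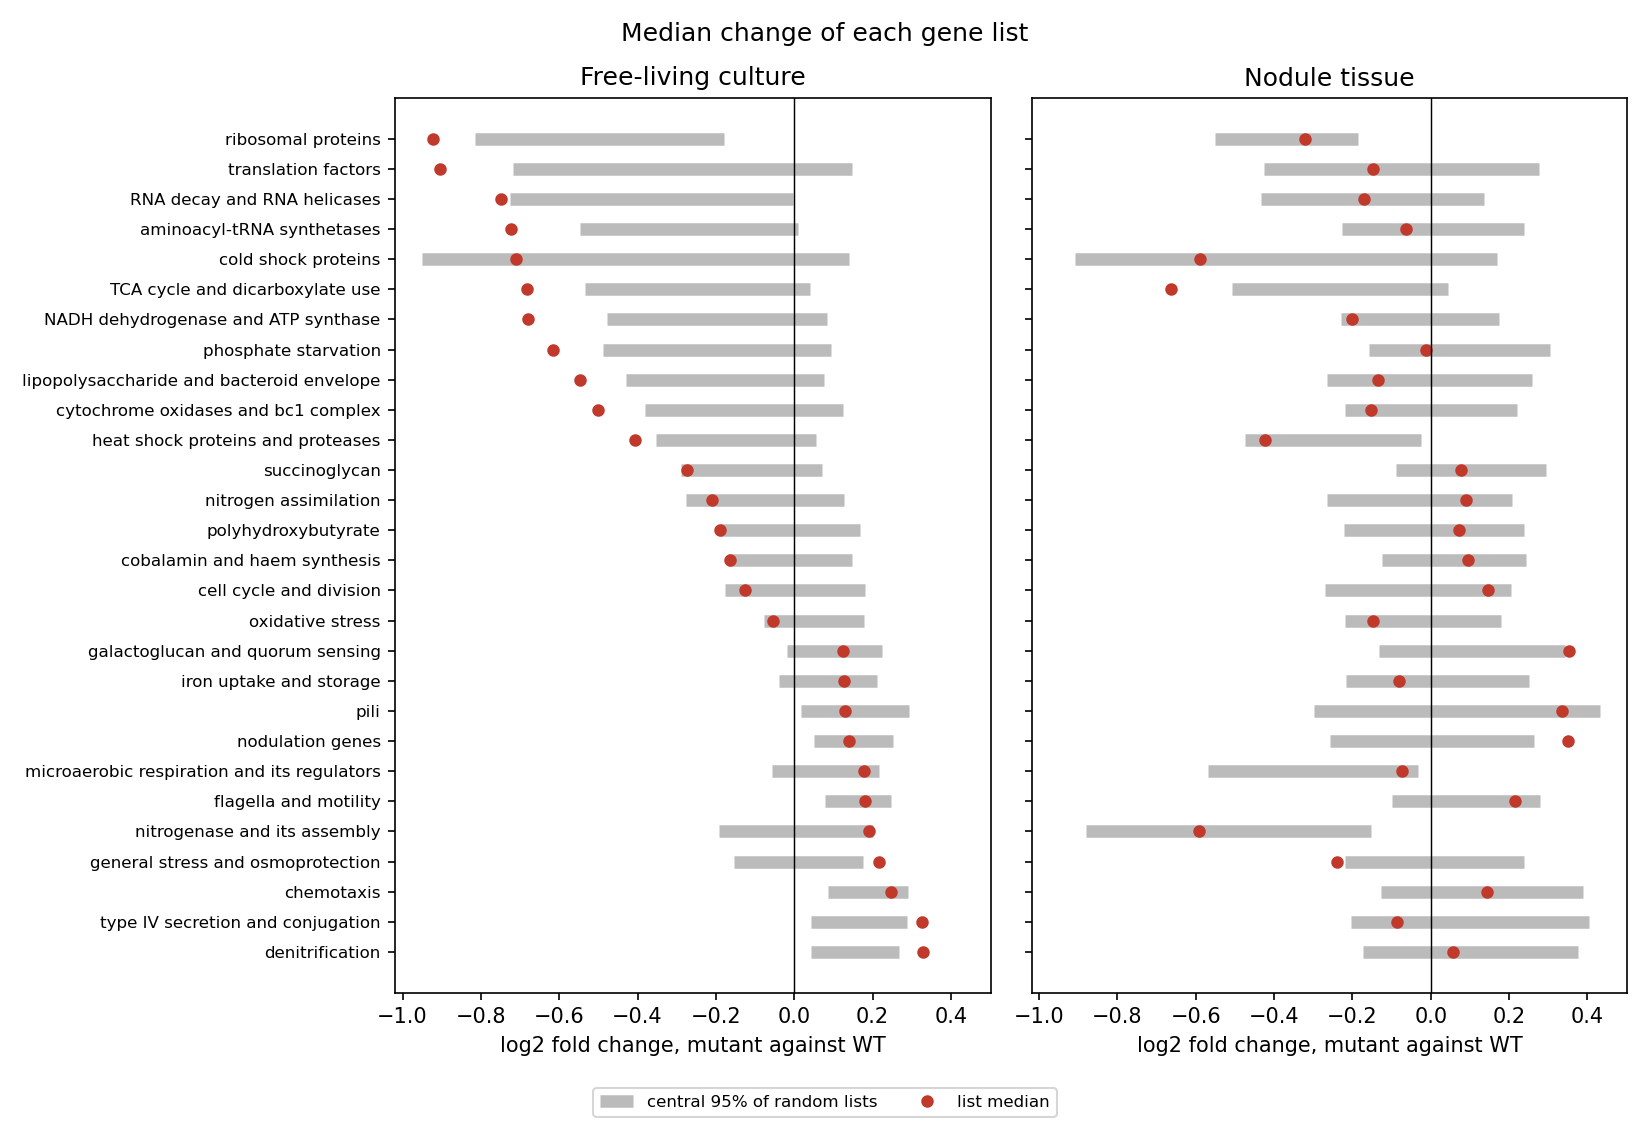
Median log2 fold change (mutant against WT, 3 libraries each) of each of the 28 gene lists as points, with grey bars for the central 95% of the medians of 10000 random lists matched on mean FPKM, in free-living culture (left) and nodule tissue (right). Ribosomal protein genes lie at -0.92 in culture and -0.32 in nodules, and denitrification genes at 0.33 in culture and 0.06 in nodules.

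The changes in free-living cells were unevenly spread over the 3 replicons. On the chromosome 248 of 3346 features changed, 24 up and 224 down (7.41% against 4.02% elsewhere, Fisher's exact test, two-sided, adjusted p = 3.12e-08). On the plasmid pSymA, which carries the nitrogenase and nodulation genes, 31 of 1314 changed, 25 up and 6 down (2.36% against 6.77%, adjusted p = 2.97e-10). On pSymB, which carries the exopolysaccharide genes, 85 of 1571 changed, 66 up and 19 down (5.41% against 5.99%, adjusted p = 0.755). The median log2 change was -0.15 on the chromosome, 0.19 on pSymA and 0.24 on pSymB. The change also went with level, since of 5 bands of mean FPKM of protein-coding features the lowest had a median of 0.24 and the highest -0.44. Within that highest band the medians were -0.62 for the chromosome, 0.12 for pSymA and 0.05 for pSymB. Neither replicon test passed with calls at 0.01 or with calls made without WT replicate 1, WT replicate 2, mutant replicate 1 or mutant replicate 2, and genes are not independent replicates.

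**Figure D3:**
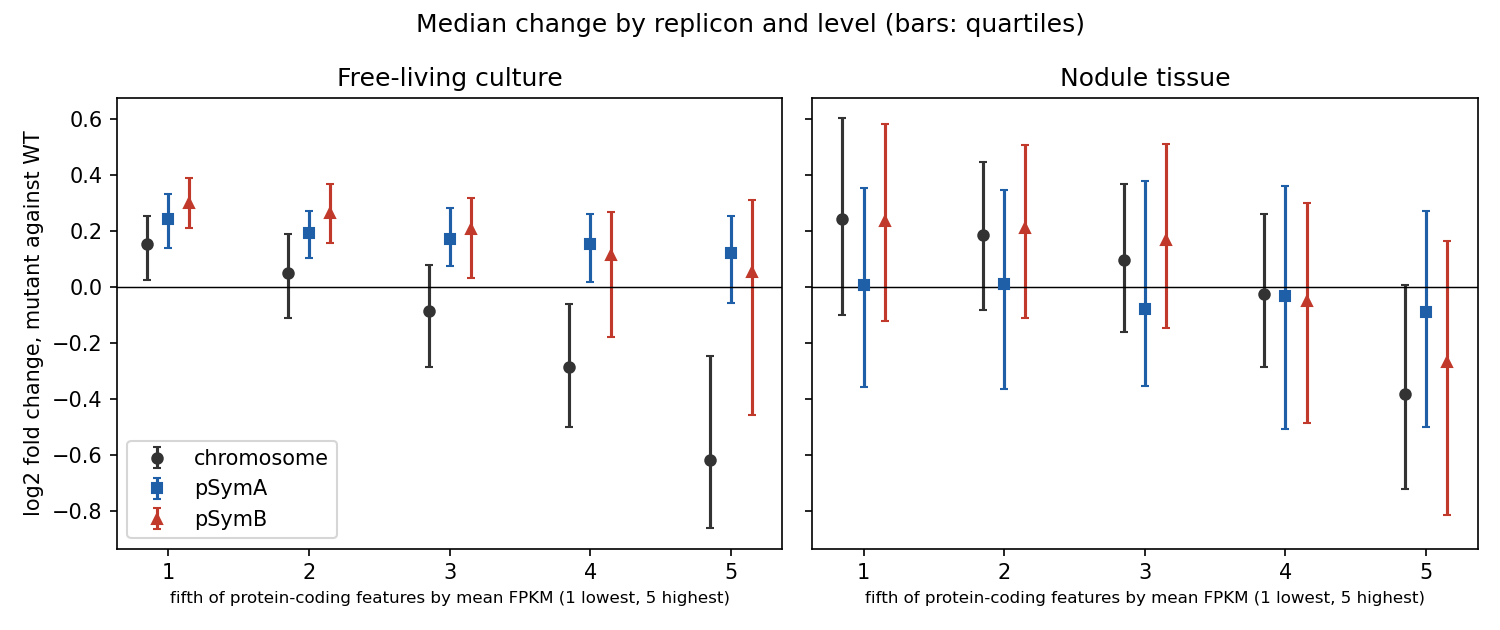
Median log2 fold change (mutant against WT, 3 libraries each) of protein-coding features of each replicon in 5 bands of mean FPKM, with bars from the lower to the upper quartile of features, in free-living culture (left) and nodule tissue (right). In the highest band of culture the chromosome lies at -0.62 and pSymA and pSymB at 0.12 and 0.05.

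The next question was which bacterial genes changed in mutant nodules. The deleted genes fell, with log2 changes of -11.82 for cspA2 (SE 0.94, edgeR adjusted p = 1.28e-05) and -11.52 for cspA4 (SE 0.97, 1.33e-05; n = 3 libraries per genotype). cspA2 had 8117, 4593 and 3638 fragments in the WT nodules and 0, 3 and 3 in the mutant nodules, and cspA4 had 24694, 9917 and 13422 against 7, 10 and 7. No other of 6361 tested features passed the threshold with edgeR, while 284 had an unadjusted p under 0.05. The other cold shock genes cspA1 (-1.19, SE 0.60), cspA3 (-0.20, SE 0.41), cspA5 (-0.42, SE 0.41), cspA6 (-0.59, SE 0.40) and cspA7 (-0.23, SE 0.35) had adjusted p of 0.999 or more. DESeq2 called 19 features, limma on log2(FPKM + 1) 4, while 165 were called in the authors' deposited table. On simulated data with the spread of these nodule libraries the test found 58% of 4-fold and 0% of 2-fold changes. In free-living culture it found 100% and 96%, in features simulated without the shifts that many genes share. Changes near 2-fold were thus not detectable in nodules with this test.

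The nitrogen fixation genes did not differ detectably between WT and mutant nodules. The nitrogenase genes nifH, nifD and nifK, of which nifD and nifK were chosen after their values were seen, had log2 changes of -1.27 (SE 1.12), -0.98 (SE 1.10) and -1.13 (SE 1.03), each with an adjusted p of 0.999, and fixA had -0.34 (SE 1.06). Of the 15 nitrogenase genes 12 lay below 0 (median -0.59, percentile 21.0 of lists of the same level), and 0 passed over all genes or adjusted over the list alone. Of the 25 genes of the TCA cycle and dicarboxylate use 20 lay below 0 (median -0.66, percentile 0.11), with gltA at -1.07 and pdhA at -0.86. Nodulation genes had a median of 0.35 (percentile 99.5), with nodD3 at 0.41 and nodL at -0.45, and galactoglucan genes of 0.35 (97.9), with mucR at -0.37 and sinR at -0.97. General stress genes had a median of -0.24 (percentile 1.7), with rpoE1 at -0.49 and rpoE3 at -0.67. Ribosomal protein genes had a median of -0.32 (percentile 75.3), with rpmG at -0.02 and rpmA at -0.08. The random lists behind these percentiles were not matched on replicon.

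Of the 28 lists only the cold shock genes held a called member in nodules, the 2 deleted genes (2 of 7, Fisher's exact test, two-sided, adjusted p = 3.08e-05), and each other list had 0 calls over all genes and adjusted over the list alone. The RNA chaperone gene hfq (-1.46, SE 0.51) and the protease gene hslV (-1.36, SE 0.55) had the largest log2 changes among the 2 most abundant members of each remaining list, with adjusted p of 0.999. Genes of stress and nutrient responses lay closer to 0, with ibpA at -0.89, irr at -1.02, rirA at -0.76, trxA at -0.52, sodB at -0.31, glnB at 0.47, glnK at 0.91, pstS at -0.40 and phnA at 0.72. So did genes of respiration, with fixK2 at 0.25, fixQ1 at -0.07, azu1 at 0.06, napE at -0.44, atpE at -0.57, atpI at -0.65, fbcF at -0.31 and fbcC at -0.52. Genes of translation, with infC at -0.04, infA at 0.22, hisS at -0.42, pheS at 0.50 and nusA at -0.27, and of the envelope, with exoX at -0.50, exoI at -0.24, acpXL at -0.49 and lpxB at 0.02, had adjusted p of 0.999 or more. The same held for motility, with visN at -0.55, fliQ at -0.67, cheY2 at -0.07, cheW2 at -0.05, pilA1 at 0.62 and pilA2 at 0.73. It also held for mraZ (-0.57), cpdR1 (0.21), phaC2 (0.23), aniA (-0.20), hemK1 (-0.88), cobT (-0.25), rctA (-0.09) and traC (0.51). The camera set test with preset correlation called 5 lists, namely the nitrogenase, ribosomal protein, heat shock and TCA cycle genes and the cold shock genes. The call of the cold shock genes ended without the 2 deleted genes (adjusted p = 0.0668). With an estimated correlation camera called 0 lists (adjusted p = 0.167 to 0.894). The directional fry test called 0, and its mixed form only the cold shock genes (adjusted p = 0.0188), which include the 2 deleted genes. Both called features, the deleted genes, lie on the chromosome, and no replicon test passed, with median log2 changes of -0.01 for the chromosome, -0.01 for pSymA and 0.14 for pSymB.

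The authors' deposited table called 165 features in nodules, 24 higher and 141 lower in the mutant, and did not call cspA2 (q = 0.618) or cspA4 (q = 0.69). Leaving out 6 calls with an FPKM of 0 in 1 genotype, the largest rises in the authors' deposited table were those of SMa0662, a Crp family regulator (log2 2.20), SMb21382 (1.90), rimI (1.89), mrcB, a penicillin-binding protein (1.72), ccsA of cytochrome c biogenesis (1.59), metC, cystathionine beta-lyase (1.57), the transport genes SMc02343 (1.52), SMb21152 (1.48) and SMc01633 (1.41), and nnrU (1.52). With the same 6 left out, the largest falls in the authors' deposited table were those of the hypothetical genes SMc00591 (-3.48), SMc00193 (-3.46) and SMc01427 (-3.45), the non-coding RNAs SMc06302 (-3.36) and SMc07040 (-2.67) and the conserved hypothetical genes SMc04164 (-3.01), SMc00348 (-3.00), SMc00933 (-2.80), SMc00181 (-2.66) and SMa0548 (-2.55). Among regulators, the authors' deposited table called hfq (-2.16), the iron response regulator irr (-1.68), the nitrogen sigma factor rpoN (-1.48), rpoE3 (-1.31), the quorum sensing regulator sinR (-1.10), betI (-1.60) and the nodulation regulator syrM (1.24). Other list members called in the authors' deposited table were grxC (-2.19), gor (-1.05), clpP1 (-1.63), acpXL (-1.93), parB (-1.61), phbA (-1.15), cycF (-1.55), cycG (1.10), lepA (-1.19) and the ribosomal protein genes rpsU1 (-2.41), rplF (-1.70), rplQ (-1.63) and rpmJ (-1.30). Ribosomal proteins had 5 of 54 members called in the authors' deposited table, and no list was enriched after adjustment (lowest adjusted p = 0.271, Fisher's exact test). Of the 160 of these calls that edgeR tested, 31.9% had all WT libraries on one side of all mutant libraries in TMM-scaled CPM. Chance gives 10% and all nodule features gave 8.96%. In culture 62.6% of such calls and 35.1% of all features were apart in this way.

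The changes in culture and in nodules were then compared. The only 2 features called in both with edgeR were cspA2 and cspA4, which follows from their deletion and tests no shared response, and 0 features rose in both or went opposite ways. Of the 119 features that rose in culture 75 lay above 0 in nodules, and of the 258 others that fell 166 lay below 0, where 48.2% of all features tested in both lay below 0 in nodules. Across 6337 features without the deleted genes, which are not independent replicates, the log2 changes of both conditions had a Pearson r of 0.19 and a Spearman rho of 0.215. The highest of 5 bands of mean FPKM had the lowest median in both conditions (-0.44 in culture, -0.33 in nodules). These comparisons were not matched on level, so a trend with level may account for part of the agreement. A limma voom interaction test over all 12 libraries called 0 of 6501 features for a genotype effect that differed between nodules and culture (378 at an unadjusted p under 0.05), and no other tool was run for it. By the authors' deposited table, 66 features were lower in both (18.7 by chance over 6564 features, Fisher's exact test, p = 1.03e-22) and 1 was higher in both. That chance value was not matched on level either, although abundant genes tended to be lower in both conditions. The p-value therefore does not show a shared response to the deletion. Those lower in both in the authors' deposited table included the DNA-binding protein gene hupB (-1.29 in culture, -1.34 in nodules), SMc00581 (-1.20, -1.45) and SMc00791 (-1.18, -1.62). SMc01427 (-1.52, -3.45) was lower in both too. Its tag directly precedes that of the deleted cspA2, so a local effect of the deletion cannot be told apart from a shared response. The 1 higher in both in the authors' deposited table was the non-coding RNA SMc06661 (1.56 in culture), listed at 0 in WT nodules. In opposite directions the authors' deposited table called 4 features that rose in culture (4.88 by chance), SMa6238, SMc03244, SMb20303 and paaE. It called 2 that fell in culture (3.18 by chance), metC and ccsA.

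Nitrogen fixation genes were far more abundant in nodules than in culture, in both genotypes. By the group FPKM of the authors' deposited table, all 15 nitrogenase genes were higher in WT nodules (median log2 ratio 6.64), as were 14 of 15 in mutant nodules (5.86), and the 26 genes of microaerobic respiration had a median of 1.98 in the WT. Ribosomal protein genes (-3.65), phosphate starvation genes (-3.26), NADH dehydrogenase and ATP synthase genes (-2.56) and succinoglycan genes (-2.38) had the lowest medians in WT nodules by the authors' deposited table, where all protein-coding features had -1.19. Heat shock and protease genes had 0.05, and this sign turned when FPKM were scaled to the same sum. The tables were normalised separately, and the nitrogenase median was 5.47 with FPKM scaled to the same sum and 7.75 with the same median. The microaerobic median was 0.81 (14 of 26 higher) and 3.10 in these scalings, and the ribosomal protein median -4.82 and -2.53. In a limma voom fit over all 12 libraries, chosen after the data were seen, 725 features were higher and 537 lower in WT nodules than in WT culture, and 670 and 411 in the mutant. In that fit all 15 nitrogenase genes rose in WT nodules and 14 rose in mutant nodules, while 48 and 41 of the 54 ribosomal protein genes fell.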

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

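Every test of an explanation in this part was chosen only after the result it addresses had been seen.

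In free-living cells the most abundant genes were lower in the mutant and scarce genes slightly higher, from a median log2 change of -0.44 in the highest of 5 bands of FPKM to 0.24 in the lowest. Nodules had a trend in the same direction, with medians of -0.328 in the highest band and 0.135 in the lowest. The tests that follow address culture only. A background spread evenly over the genome was excluded as the whole cause, because the abundant features of pSymA and pSymB had a median of 0.00456 against -0.628 (95% range -0.666 to -0.569) for random chromosomal lists of the same FPKM, percentile 100, although an earlier form of that test, dropped after it was seen, gave percentile 2.27 for the ribosomal protein genes (-0.923 against a random median of -0.826, in lists that could hold the same genes) and decided nothing. The values argue against a loss of short genes as the whole cause, because among the abundant features the longer ones changed more than the shorter ones. The medians were -0.723 and -0.204 (ratio 3.54, 95% bootstrap interval 2.71 to 5.73). The longer and shorter features were not matched on level or replicon, so a part played by such a loss is not excluded. An earlier test with matching on length and coarser matching on level was dropped. It gave percentile 0 for the ribosomal protein genes (-0.923 against a random median of -0.54). A loss of long genes was not tested. The lower depth of the mutant libraries was excluded by thinning, which left the most abundant 5% at -0.824 against -0.828 before. A difference between libraries that is also present within one genotype fits. WT replicate 3 minus WT replicate 1 correlated at r = 0.733 across 6480 features with the mutant change measured on the other libraries. In absolute value, WT replicates 2 and 3 gave 0.734, WT replicates 1 and 2 0.22, and the mutant pairs 0.518, 0.539 and 0.0609. A difference between replicates, whether of growth or not, may therefore account for part of the pattern. The labels do not say whether replicates were separate cultures. An effect of genotype on the same genes stays open, because no test here separates it from such a difference.

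The authors' deposited table calls 165 features in nodules where edgeR calls 2. Of the 160 that edgeR tested, 31.9% had all WT libraries on one side of all mutant libraries, where all nodule features gave 8.96% and chance gives 10%, against 62.6% of such calls and 35.1% of all features in culture. The sides were judged on TMM-scaled CPM, not on the FPKM of the authors' deposited table. On that scale this fits calls made where the libraries of the genotypes overlap, and 76 of the 160 had an unadjusted edgeR p under 0.05. Some of the 165 may still be real changes that 3 libraries per genotype could not separate, given that 58% of simulated 4-fold changes were found.

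Of the 10 possible splits of the 6 libraries into 3 against 3, only 1 gave as many calls as the real grouping in culture (379, highest other split 0) and only 1 in nodules (2, highest other 0), and 10 splits are too few for a test.

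The genotype effect of 10 lists differed between nodules and culture by camera with the preset correlation, while with an estimated correlation none did. General stress and osmoprotection genes had an adjusted p of 0.00722 (0.0981 with the estimated correlation), a median difference of -0.48, and medians of 0.22 in culture and -0.24 in nodules. Aminoacyl-tRNA synthetase genes had an adjusted p of 0.00815 (0.784 with the estimated correlation) and a median difference of 0.46. Nitrogenase and assembly genes had an adjusted p of 0.0104 (0.784) and a median difference of -0.94. Phosphate starvation genes had an adjusted p of 0.0132 (0.784) and a median difference of 0.66. Cytochrome oxidase and bc1 genes had an adjusted p of 0.0132 (0.784) and a median difference of 0.55. RNA decay and RNA helicase genes had an adjusted p of 0.0229 (0.784) and a median difference of 0.60. Cobalamin and haem synthesis genes had an adjusted p of 0.0393 (0.784) and a median difference of 0.37. Denitrification genes had an adjusted p of 0.0432 (0.784) and a median difference of -0.32. Ribosomal protein genes had an adjusted p of 0.0432 (0.88) and a median difference of 0.39. Succinoglycan genes had an adjusted p of 0.0488 (0.784) and a median difference of 0.20.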

How the results depend on the processing

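The falls of cspA2 and cspA4 kept their direction and their call under every alternative in culture, and in nodules under all but the authors' deposited calls. No named gene reversed. The planned main test, the authors' calls, and its fallback, limma, became alternatives after the data were seen. DESeq2, RLE scaling, the fits without a low-count filter, with protein-coding features only or thinned libraries, and the leave-one-out values of lists, overlap and replicons were chosen after the data were seen. The cause was not tested for any of the shifts given here, except that a stricter threshold, a least fold or a left-out library gives fewer calls or samples by construction.

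In culture the count of 379 became 10 at a threshold of 0.01, 75 with a log2 change of at least 1, 87 with that change computed on FPKM plus 1, and 12 adjusted over both tables together. It was 19 with RLE scaling, 1953 with DESeq2, 4 with limma on log2(FPKM + 1), 1104 in the authors' deposited calls and 3 to 2720 with 1 library left out. Of the 66 called features named, 55 lost their call with RLE scaling, 56 with the joint adjustment, 63 with limma, 21 in the authors' deposited calls and 1 with thinned libraries. In nodules the count of 2 became 19 with DESeq2, 4 with limma and 165 in the authors' deposited calls, and stayed at 2 without any 1 library. The lists that passed in culture, 1 in the main result, were 2 at 0.01, 3 with a log2 change of at least 1, 1 to 12 with 1 library left out, 12 in the authors' deposited calls and 10 with DESeq2. That 1 list, the cytochrome oxidases, was not among those passing at 0.01 or without WT replicate 2, mutant replicate 1 or mutant replicate 2, and the cold shock genes that passed there were called through the 2 deleted genes alone. In nodules 1 list passed and 0 did in the authors' deposited calls. The overlap of 2 falls became 66 in the authors' deposited calls and 8 with DESeq2. The 2 replicon tests that passed became 0 at 0.01, 0 to 3 with 1 library left out and 6 in the authors' deposited calls.

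With the replicate number as a replicate block, 10 features changed in culture and 12 in nodules, 2 lists passed in each condition, 0 replicon tests passed, and 3 falls were shared. In culture the numbers do not pair the libraries, since deviations of libraries with the same number correlated at -0.533, -0.0746 and -0.64. In nodules libraries with the same number correlated at 0.181, 0.21 and -0.01. Between numbers 1 and 2 the crossed nodule pairs gave -0.189 and -0.211, so pairing is not settled there.

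Free-living mutant libraries were shallower than WT libraries, and thinning all to the same depth gave 532 calls, 357 of them among the 379. In nodules, at the depth and spread of these libraries together, 0% of simulated 2-fold changes were found.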

Other observations

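The values in this part were chosen after the data were seen.

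SMc01427, a hypothetical gene whose locus tag directly precedes that of cspA2, had a log2 change of -1.42 in culture (SE 0.15, adjusted p = 0.00302, place 12 of 6482 from the lowest) and -2.20 in nodules (SE 0.39, adjusted p = 0.0844, place 30 of 6361). In the authors' deposited table its nodule q was 0.00599. No test here separates a local effect of the deletion from a response to the loss of the protein. The other neighbouring tag of cspA2, SMc01429, had -0.27 in culture and 0.24 in nodules. Beside cspA4, SMc04233 had -0.47 in culture (SE 0.18, adjusted p = 0.091) and -0.69 in nodules (SE 0.47), and SMc04235 had -0.34 (SE 0.13, adjusted p = 0.0942) and -0.45 (SE 0.36), with nodule adjusted p of 0.999. The authors' deposited table called both in culture (q = 0.00101 and 0.0322) and neither in nodules.

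On the first principal component of the free-living libraries (74.2% of the variance) the WT libraries lay at -32.3, -19.8 and -0.193 and the mutant libraries at 26.6, 19.6 and 6.1. The 10 most abundant features took 6.36% to 12.9% of the fragments in culture and 34.5% to 53.7% in nodules. The authors' deposited table called 5 features in culture and 6 in nodules that had a group FPKM of 0 in 1 genotype.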
